A study of Homo sapiens with 12 samples.

How the data were processed

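RNA of SK-MEL-2 cells was measured on 12 Affymetrix arrays, 3 in each of 4 treatment groups, 24 hours after treatment. Per the labels, ERCC spike-in mix was added before RNA extraction. The deposited values are linear intensities per probe set, between 2.345 and 8595, made with RMA and Transcriptome Analysis Console per the submitters' processing notes, which give no version or order. RMA normally ends on a log2 scale with arrays on a common distribution. The deposited arrays were not on one, with medians from 16.8 to 31.9, and the step that rescaled them is not given in the sources used here. Whether that step used the spike-ins is not known. The design written before the data were examined assumed log2 values, so log2 was taken here with no pseudocount and no filter. No genome build was used, so no positions are given. The number of arrays limits the precision.

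Of 29398 probe sets, 14750 (50.2%) were named for 1 gene, through a table of probe sets and gene identifiers and RefSeq symbols, and 14648 were not named here and stayed out of the gene tests. Where a gene had several probe sets (156 genes), the one with the highest mean over the 12 arrays stood for it, which left 14582 genes. Probe sets of these genes were called in opposite directions for 1, 0, 4, 1, 1 and 0 genes in the 6 comparisons. Probes of close relatives, such as metallothioneins, and of pseudogenes such as AQP7P1 can bind transcripts of more than 1 gene, which was not tested. Of 27 genes fixed in advance to be named, 17 are reported and 10 are not analysed here.

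All 12 arrays were fitted with 1 mean per group in limma 3.58.1 (R 4.3.3, lmFit and eBayes). The 6 comparisons were each treatment against DMSO, all 3 agents against DT and against E, and the interaction, which is the difference between DTE and DT minus the difference between E and DMSO. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Gene lists (41 lists with 1011 entries, 585 of them measured) were tested with limma's camera at a preset correlation of 0.01, in lists with at least 5 measured genes, and adjusted over 38 lists. Camera compares a list with all other genes. In deposited values none of the called lists kept its call with a correlation estimated from the data, and after quantile normalization 8, 2, 7, 1, 10 and 4 lists did in the 6 comparisons, in the order above. Overall array levels were compared with exact permutation tests.

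The tests, lists, comparisons, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 10 largest rises and falls in each comparison with DMSO and the 6 largest in the others. They come from genes past the threshold whose highest group mean was above the median gene and, except for the interaction, whose arrays did not overlap between groups. It adds up to 4 members with the smallest adjusted p of each list described, and the genes fixed in advance. Genes without an established name were skipped. An arm counted as not well above background for a gene when its mean did not exceed the 95th percentile of the dimmest 25% of genes (11.1 to 16.2 on single arrays), a rule chosen after the values were seen, and the bound takes that level for the dimmer arm. Which lists are described, and in which comparisons, was chosen after their values were seen. Quantile normalization was planned for the counts of genes, and was extended to lists, single genes and correlations after the arrays were seen to differ in level, as were median centring of single genes and centring on the brighter part of the genes. Other alternatives were leaving out each array, a replicate block, fitting only the groups compared, another variance model, array weights, filters on dim genes, other treatments of several probe sets, fry, and an estimated correlation.

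The procedure was tested on values simulated around each gene's mean over all 12 arrays, with its estimated variance, normal noise and no correlation between genes. Of changes of 0.5 on the log2 scale added to the DT arrays 40.3% were called, and 100% of changes of 1 and of 2, with 5 calls among 14382 unchanged genes. Simulated differences in array level alone, of the size seen within groups and put on the brighter genes, gave at most 1 call in DTE vs DMSO among 14582 genes in 20 simulations. The simulated noise already held that spread in level, which was thus counted 2 times and widened the errors. The simulation therefore cannot tell how many calls such level differences give. Nor can the regrouped residuals below, which still held the interaction. Values left out of the comparisons are the probe sets not named here and lists with fewer than 5 measured genes, of which there were 3.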

Results

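Gene expression was measured on 12 Affymetrix arrays of SK-MEL-2 cells, an established human melanoma line, after 24 hours of treatment. A 2 x 2 design crossed inhibition of the MAPK pathway with inhibition of histone deacetylases, and each of the 4 arms held 3 arrays. The arms were vehicle (DMSO), dabrafenib at 100 nM with trametinib at 10 nM (DT), entinostat at 1 µM (E), and all 3 agents (DTE). Dabrafenib inhibits RAF kinases, trametinib inhibits MEK1 and MEK2, and entinostat inhibits class I histone deacetylases. The design asks what each treatment changes, what each adds to the other, and whether their effects add up. The sample titles call the replicates biological and the series text calls them technical, so p-values measure only the spread between these arrays, and 3 arrays per arm limit the precision. Arrays of 1 arm correlated across genes at 0.991 to 0.994 and arrays of different arms at 0.956 to 0.981, where genes are not independent replicates. No array duplicated another. Differences are on the log2 scale with the standard error (SE) of the fit, and the difference after quantile normalization of the arrays follows as the quantile value. Where the dimmer arm was not well above the estimated background, only a lower bound is given, as at least so many fold. The interaction joins 4 arms and was not checked in this way. Rose and fell refer to deposited values with an adjusted p under 0.05 unless quantile normalization is named.

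The arrays did not share an overall level. The geometric mean intensity of the brighter part of the genes was 129 ± 15 in DMSO, 103 ± 7.22 in DT, 143 ± 18.7 in E and 65.5 ± 3.78 in DTE (mean ± SD, n = 3 each), so that DTE stood at 50.8% of DMSO. Each of the 3 DTE arrays, at 61.2, 66.7 and 68.5, lay below each of the other 9 arrays. The exact permutation p between DTE and DMSO was 0.1, the smallest that 3 arrays against 3 allow (two-sided). Across both entinostat states, dabrafenib plus trametinib changed the level by -0.72 on the log2 scale, with a stratified exact permutation p of 0.005, the smallest that 400 regroupings allow. Entinostat across both states gave -0.25 (exact p = 0.12). Both averages join unlike effects. Dabrafenib plus trametinib changed the level by -0.32 without entinostat and by -1.12 with it. Entinostat changed it by 0.15 alone and by -0.65 on top of dabrafenib plus trametinib. The interaction of the level was -0.80, for which no test was run. The shift depended on intensity: from DMSO to DTE the median log2 difference was -0.07 in the dimmest genes and -1.09 in the brightest ones. From DMSO to DT these values were 0.004 and -0.33, and from DMSO to E 0.11 and 0.06. Over all genes the median difference was -0.12 for DT, 0.14 for E and -0.54 for DTE against DMSO, -0.41 for DTE against DT, -0.82 for DTE against E and -0.63 for the interaction. How the deposited values were rescaled between arrays is not stated, so every change is also given relative to this shift, as the quantile value.

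**Figure D1:**
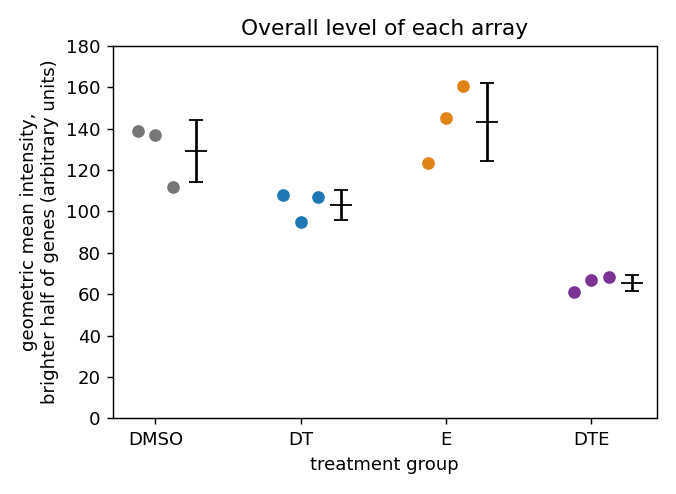
Geometric mean intensity of the brighter part of the genes on each of the 12 arrays (points, linear axis from 0, arbitrary units) by treatment group, with the mean and SD of 3 arrays beside them. The 3 DTE arrays sit between 61.2 and 68.5, below all other arrays.

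**Figure D2:**
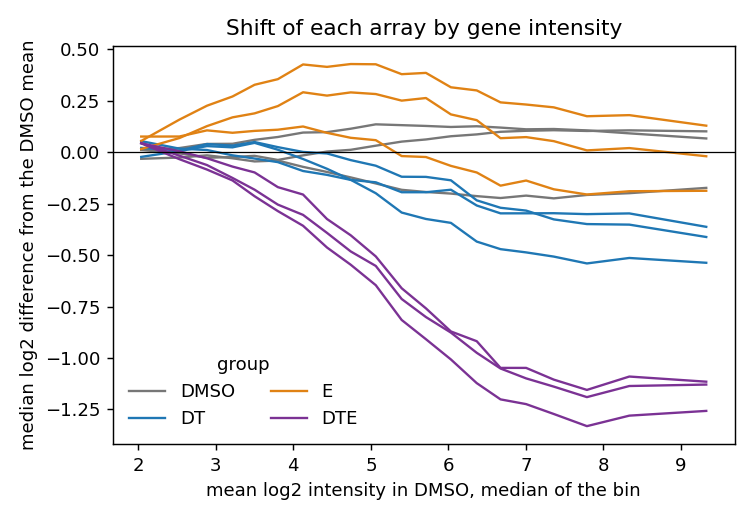
Median log2 difference of each array from the DMSO mean (vertical axis) in 20 bins of genes ordered by their mean log2 intensity in DMSO (horizontal axis), 1 line per array, coloured by group. The lines of the DTE arrays fall with intensity and those of the DT arrays fall less far, while lines of all groups meet near 0 for the dimmest genes.

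Dabrafenib plus trametinib lowered the genes that report RAF-MEK-ERK signalling. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, dropped from an intensity of 904 ± 130 in DMSO to 55 ± 8.23 in DT (SD, n = 3), 16.5-fold (-4.04 ± 0.17, quantile -3.69). The ETS factors ETV4 (-3.11 ± 0.15, quantile -2.72) and ETV5 (-1.98 ± 0.15, quantile -1.60), the phosphatases DUSP4 (-2.71 ± 0.16, quantile -2.32) and DUSP6 (-1.12 ± 0.13, quantile -0.78), the transcription factor MYC (-2.57 ± 0.17, quantile -2.18) and cyclin D1, CCND1 (-1.37 ± 0.14, quantile -1.01), fell as well. Of the measured genes of the RAF-MEK-ERK output list, 21 of 23 fell (22 adjusted over the list alone) and 0 rose, with a median of -1.20 (camera adjusted p = 5.8e-17, and adjusted p = 0.29 with an estimated correlation). In quantile-normalized values 18 fell, with a median of -0.83 (adjusted p = 4.8e-16, and adjusted p = 7.0e-04 with an estimated correlation). The largest fall among genes that met the naming rule was that of UCN2, which encodes the peptide urocortin 2 (-4.30 ± 0.17, quantile -3.995), followed among genes outside the list by NPPC (-2.91 ± 0.18, quantile -2.57), ANKS1A (-2.76 ± 0.16, quantile -2.40), ZNF114 (-2.66 ± 0.16, quantile -2.24), RLBP1 (-2.49 ± 0.18, quantile -2.14) and the non-coding LINC00520 (-2.45 ± 0.15, quantile -2.07).

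Proliferation genes fell together. Of the mitosis genes 29 of 29 fell (29 adjusted over the list alone), with a median of -1.31. Among them were AURKB (-1.86 ± 0.13, quantile -1.52), CDK1 (-1.95 ± 0.15, quantile -1.59), MAD2L1 (-1.99 ± 0.14, quantile -1.59) and CCNF (-1.64 ± 0.15, quantile -1.27). In the replication list 18 of 19 fell (18 adjusted over the list alone), with a median of -1.64. They were led by GINS2 (-2.32 ± 0.15, quantile -1.93), MCM10 (-2.19 ± 0.16, quantile -1.79), CDC45 (-2.01 ± 0.14, quantile -1.65) and MCM3 (-1.94 ± 0.14, quantile -1.58). Of the ribosome biogenesis genes 26 of 26 fell (26 adjusted over the list alone), with a median of -1.09. They included LYAR (-2.01 ± 0.14, quantile -1.65), BOP1 (-1.57 ± 0.14, quantile -1.23), NOB1 (-1.41 ± 0.14, quantile -1.06) and NOLC1 (-1.35 ± 0.13, quantile -1.03). In the list of G1 control genes 16 of 18 fell (16 adjusted over the list alone), with a median of -1.06. Among them were CDK2 (-1.94 ± 0.15, quantile -1.58), E2F1 (-1.91 ± 0.16, quantile -1.54), E2F7 (-1.78 ± 0.14, quantile -1.39) and CDC25A (-1.75 ± 0.15, quantile -1.39). Camera adjusted p was 1.3e-23 for mitosis, 5.7e-22 for replication, 1.1e-18 for ribosome biogenesis and 2.5e-10 for G1 control. With an estimated correlation the adjusted p values were 0.23, 0.23, 0.36 and 0.38, in that order. In quantile-normalized values 29, 18, 26 and 13 members fell, with medians of -0.95, -1.29, -0.72 and -0.75. There the 4 lists kept adjusted p values of 0.0033, 0.001, 2.7e-04 and 0.0013 with an estimated correlation.

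DNA repair genes fell in part. In homologous recombination 18 of 24 fell (20 adjusted over the list alone), with a median of -0.82 (camera adjusted p = 2.5e-10, and adjusted p = 0.38 with an estimated correlation). Among them were XRCC2 (-2.11 ± 0.16, quantile -1.73), RAD54L (-1.95 ± 0.16, quantile -1.61), RAD51AP1 (-1.81 ± 0.14, quantile -1.54) and the exonuclease EXO1 (-1.77 ± 0.15, quantile -1.41). After quantile normalization 16 of these genes fell and 1 rose (adjusted p = 2.8e-08, and adjusted p = 0.0047 with an estimated correlation). Of the damage checkpoint genes 12 of 14 fell (13 adjusted over the list alone), with a median of -0.96 (camera adjusted p = 1.6e-07, and adjusted p = 0.38 with an estimated correlation). They were led by CLSPN (-1.80 ± 0.14, quantile -1.43), CHEK1 (-1.36 ± 0.14, quantile -0.97), TIMELESS (-1.43 ± 0.16, quantile -1.08) and TOPBP1 (-1.21 ± 0.16, quantile -0.83). The quantile median of that list was -0.62 (adjusted p = 4.8e-06, and adjusted p = 0.041 with an estimated correlation). In base excision repair 11 of 17 fell (13 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 6.1e-05, and adjusted p = 0.62 with an estimated correlation). Among them were NEIL3 (-1.57 ± 0.15, quantile -1.28), UNG (-1.36 ± 0.15, quantile -0.99), NTHL1 (-1.25 ± 0.15, quantile -0.89) and PARP2 (-1.09 ± 0.15, quantile -0.70). Its quantile median was -0.11 (adjusted p = 0.0013, and adjusted p = 0.024 with an estimated correlation). XRCC5, which encodes the Ku80 end-joining factor, fell in the deposited values (-0.45 ± 0.13, quantile -0.13), although not past the threshold after quantile normalization (adjusted p = 0.23). XRCC4, the end-joining scaffold, measured -0.06 ± 0.13 in deposited values and 0.31 in quantile-normalized values (adjusted p = 0.82 and 0.03). MGMT, which reverses alkylation of guanine, measured -0.03 and 0.15 (adjusted p = 0.92 and 0.33).

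Of the melanocyte differentiation genes 9 of 17 fell (9 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.03, and adjusted p = 0.71 with an estimated correlation). They included MITF, the regulator of the melanocyte lineage, (-2.09 ± 0.15, quantile -1.73), its targets MLANA (-0.95 ± 0.15, quantile -0.59) and GPR143 (-1.22 ± 0.18, quantile -0.93), and CDK2, a cell cycle kinase that the list holds as an MITF target. After quantile normalization 6 fell and 3 rose (adjusted p = 0.16). The largest rise was that of ANGPTL7, a secreted angiopoietin-like protein, from 107 ± 9.19 to 2601 ± 178 (SD, n = 3), 24.4-fold (4.61 ± 0.18, quantile 4.95). Others that rose were the pseudogene AQP7P1 (3.04 ± 0.17, quantile 3.19), LCTL (2.82 ± 0.13, quantile 3.10), the autophagy paralog MAP1LC3C (2.58 ± 0.14, quantile 2.64), MROCKI (2.29 ± 0.15, quantile 2.33), ASPA (at least 2.82-fold, quantile at least 2.91-fold), the AP-1 subunit JUN (2.19 ± 0.14, quantile 2.55), GLIS3 (2.07 ± 0.15, quantile 2.20), TXNIP (2.06 ± 0.18, quantile 2.33) and ARHGEF6 (1.98 ± 0.18, quantile 2.11). In the quiescence list 6 of 13 rose (6 adjusted over the list alone) and 1 fell (camera adjusted p = 0.007, and adjusted p = 0.71 with an estimated correlation). TXNIP, KLF9 (0.77 ± 0.16, quantile 1.02) and CCNG2 (0.76 ± 0.15, quantile 1.00) rose, while lamin B1, LMNB1 (-1.66 ± 0.16, quantile -1.28), fell, and the quantile median was 0.46 (adjusted p = 0.0022, and adjusted p = 0.12 with an estimated correlation). YAP-TEAD targets and histone deacetylases were called only after quantile normalization. There the YAP-TEAD list had 7 of 13 genes higher (7 adjusted over the list alone) and 2 lower (adjusted p = 0.018, and adjusted p = 0.17 with an estimated correlation). Examples were AJUBA (1.22 ± 0.13, quantile 1.28) and AMOTL2 (0.89 ± 0.13, quantile 1.18). In deposited values 5 were higher and 2 lower, with a median of -0.07 and a mean of 0.06 (adjusted p = 0.091). For the histone deacetylases and sirtuins the quantile counts were 9 of 18 genes higher (9 adjusted over the list alone) and 1 lower (adjusted p = 0.0049, and adjusted p = 0.099 with an estimated correlation). In deposited values 5 were higher and 2 lower, with a median of -0.07 and a mean of 0.02 (adjusted p = 0.1). Among those that rose were HDAC9 (0.75 ± 0.14, quantile 0.98), HDAC5 (0.66 ± 0.15, quantile 1.02) and HDAC11 (0.58 ± 0.15, quantile 0.89).

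Of the 17 genes named in advance and measured, 11 fell and 0 rose in deposited values, against 9 and 2 after quantile normalization. MAP2K1, which encodes MEK1, fell (-0.66 ± 0.14, quantile -0.28), and HDAC2 fell in deposited values (-0.45 ± 0.16, quantile -0.21), short of the threshold after quantile normalization (adjusted p = 0.15). The pro-apoptotic BCL2L11 (-0.13 ± 0.15, quantile 0.23) changed sign and passed the threshold only after quantile normalization (adjusted p = 0.043). Between DT and DMSO, 4056 of 14582 genes passed limma's moderated test in deposited values, 688 higher and 3368 lower, of which 114 and 618 differed at least 2-fold. After quantile normalization 2199 were higher and 2130 lower, with 203 and 245 at least 2-fold, and 67.8% of the deposited calls were called again in the same direction.

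Entinostat raised genes of the neuronal list together with genes of many other kinds. STC1, which encodes the hormone stanniocalcin 1, rose from an intensity of 18.9 ± 4.9 to 428 ± 11.4 (SD, n = 3), 23.2-fold (4.54 ± 0.17, quantile 4.15). Other rises were those of TSPAN13 (4.12 ± 0.16, quantile 3.73), the protocadherin PCDH10 (3.47 ± 0.15, quantile 3.14), EBLN1 (at least 6.4-fold, quantile at least 4.63-fold), the neuronal kinesin KIF5C (3.43 ± 0.16, quantile 2.99), the thymosin TMSB15A (3.41 ± 0.15, quantile 3.35), the glutathione transferase GSTA2 (at least 3.94-fold, quantile at least 2.88-fold), the macrophage growth factor receptor CSF1R (3.03 ± 0.16, quantile 2.68), COXFA4L3 (3.00 ± 0.15, quantile 2.70) and the plastin PLS1 (2.79 ± 0.16, quantile 2.44). Of the measured genes of the neuronal list, 20 of 28 rose (20 adjusted over the list alone) and 0 fell, with a median of 1.19 (camera adjusted p = 5.4e-13, and adjusted p = 0.89 with an estimated correlation). They included DPYSL5 (at least 5.27-fold, quantile at least 3.79-fold), synapsin 1, SYN1 (2.57 ± 0.17, quantile 2.25), the microtubule-associated MAP2 (2.48 ± 0.15, quantile 2.30) and synaptotagmin 1, SYT1 (1.66 ± 0.14, quantile 1.27). In quantile-normalized values 19 rose and 1 fell (adjusted p = 9.4e-11, and adjusted p = 0.0018 with an estimated correlation).

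Receptor tyrosine kinases moved in both directions. In that list 12 of 20 rose (15 adjusted over the list alone) and 3 fell (camera adjusted p = 0.0033, and adjusted p = 0.89 with an estimated correlation). There were rises of MERTK (1.89 ± 0.16, quantile 1.55), FGFR1 (at least 3.3-fold, quantile at least 2.46-fold) and INSR (1.71 ± 0.16, quantile 1.28) and a fall of ERBB3 (-1.19 ± 0.14, quantile -1.29). The quantile counts were 9 and 3 (adjusted p = 0.0036, and adjusted p = 0.2 with an estimated correlation). Of the ribosome biogenesis genes 11 of 26 fell (11 adjusted over the list alone) and 0 rose (camera adjusted p = 1.2e-09, and adjusted p = 0.89 with an estimated correlation). Among them were WDR74 (-0.75 ± 0.15, quantile -0.92), NIP7 (-0.70 ± 0.14, quantile -0.75), NOB1 (-0.67 ± 0.14, quantile -0.73) and RRP12 (-0.61 ± 0.14, quantile -0.70). After quantile normalization 18 of the 26 fell (adjusted p = 1.5e-07, and adjusted p = 0.0037 with an estimated correlation). Other lists were called only after quantile normalization, none of them with an estimated correlation. Sterol synthesis had 8 of 17 genes higher (9 adjusted over the list alone) and 2 lower (adjusted p = 0.011, and adjusted p = 0.22 with an estimated correlation), with STARD4 (1.69 ± 0.15, quantile 1.56), MSMO1 (0.99 ± 0.16, quantile 0.90) and SQLE (0.83 ± 0.14, quantile 0.67). YAP-TEAD targets had 6 of 13 genes higher (7 adjusted over the list alone) and 1 lower (adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation), with ANKRD1 (1.62 ± 0.15, quantile 1.64), CRIM1 (0.98 ± 0.14, quantile 0.91) and CCN2 (0.67 ± 0.14, quantile 0.62). Genes known to rise with class I inhibitors had 5 of 11 genes higher (5 adjusted over the list alone) (adjusted p = 0.035, and adjusted p = 0.28 with an estimated correlation). They included clusterin, CLU (1.75 ± 0.14, quantile 1.32), SYT11 (1.15 ± 0.15, quantile 1.08) and the metallothioneins MT1X (0.99 ± 0.17, quantile 0.92) and MT2A (0.69 ± 0.15, quantile 0.62). Mitosis had 11 of 29 genes higher (11 adjusted over the list alone) (adjusted p = 0.013, and adjusted p = 0.37 with an estimated correlation). In deposited values 8 sterol synthesis, 8 YAP-TEAD, 5 inhibitor-induced and 11 mitosis genes rose, without a call of these lists.

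Falls with entinostat included those of PRR7-AS1 (-2.35 ± 0.16, quantile -2.43), TRIM48 (-2.28 ± 0.20, quantile -2.33), ANKS1A (-1.95 ± 0.16, quantile -2.04), the glycosyltransferase GALNT3 (at least 3.14-fold, quantile at least 3.25-fold), RTP4 (-1.84 ± 0.16, quantile -1.88), MIR181A2HG (-1.80 ± 0.15, quantile -1.83), LINC01531 (-1.80 ± 0.21, quantile -1.92), ANGPTL7 (-1.64 ± 0.18, quantile -1.71), LINC01239 (-1.57 ± 0.17, quantile -1.69) and JADE2 (-1.55 ± 0.18, quantile -1.62). MYC fell 2.56-fold (-1.35 ± 0.17, quantile -1.45), SPRY4 fell (-0.57 ± 0.17, quantile -0.64) and MLANA fell (-0.54 ± 0.15, quantile -0.62). The entinostat targets HDAC1 (0.51 ± 0.15, quantile 0.41), HDAC2 (0.46 ± 0.16, quantile 0.20) and HDAC3 (0.52 ± 0.14, quantile 0.43) rose in deposited values, HDAC2 not past the threshold after quantile normalization (adjusted p = 0.17). MAP2K1, which encodes MEK1, (0.53 ± 0.14, quantile 0.46) and the pro-apoptotic BCL2L11 (0.61 ± 0.15, quantile 0.51) rose. No change passed the threshold in deposited values for MITF (-0.39 ± 0.15, quantile -0.46), XRCC4 (-0.10 ± 0.13, quantile -0.18), XRCC5 (-0.12 ± 0.13, quantile -0.19), MGMT (0.13 ± 0.15, quantile -0.15), MAP2K2 (0.20 ± 0.18, quantile -0.05), DUSP4 (0.04 ± 0.16, quantile -0.02), DUSP6 (0.26 ± 0.13, quantile 0.18), ETV5 (-0.00 ± 0.15, quantile -0.08) or CCND1 (0.00 ± 0.14, quantile -0.06), where the sign for MGMT, MAP2K2, DUSP4 and CCND1 turned negative after quantile normalization. The MITF difference passed after quantile normalization (adjusted p = 7.6e-04). Between E and DMSO, 3734 of 14582 genes passed limma's moderated test in deposited values, 3033 higher and 701 lower, of which 625 and 63 differed at least 2-fold. After quantile normalization 2200 were higher and 2380 lower, with 354 and 95 at least 2-fold, and 73.3% of the deposited calls were called again in the same direction.

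With all 3 agents, UCN2 fell 45-fold (-5.49 ± 0.17, quantile -4.57) and SPRY4 26.6-fold (-4.73 ± 0.17, quantile -3.77), while STC1 (3.12 ± 0.17, quantile 3.89), TSPAN13 (3.04 ± 0.16, quantile 3.79) and PCDH10 (3.02 ± 0.15, quantile 3.81) rose, each by more than 3 on the log2 scale. Rises also included GSTA2 (at least 4.12-fold, quantile at least 6.67-fold), JAKMIP2 (at least 4.23-fold, quantile at least 6.91-fold), CCDC110 (at least 4.41-fold, quantile at least 7.21-fold), filaggrin, FLG (2.67 ± 0.16, quantile 3.50), EBLN1 (at least 3.48-fold, quantile at least 5.59-fold), KIF5C (2.47 ± 0.16, quantile 3.22) and the axon guidance factor SLIT2 (at least 3.3-fold, quantile at least 5.27-fold). Falls also included TRIM48 (-3.54 ± 0.20, quantile -2.85), PRR7-AS1 (-3.46 ± 0.16, quantile -2.67), RLBP1 (-3.43 ± 0.18, quantile -2.47), ANKS1A (-3.41 ± 0.16, quantile -2.32), LINC02946 (-3.11 ± 0.23, quantile -2.43), the polycomb factor PHF19 (-3.02 ± 0.14, quantile -2.02), SCFD2 (-3.02 ± 0.16, quantile -1.90) and ZNF114 (-2.98 ± 0.16, quantile -2.09). In the neuronal list 11 of 28 rose (11 adjusted over the list alone) and 5 fell (camera adjusted p = 2.7e-13, and adjusted p = 0.58 with an estimated correlation). After quantile normalization 19 rose and 0 fell, with a median of 1.13 (adjusted p = 5.9e-10, and adjusted p = 0.0013 with an estimated correlation). Examples were MAP2 (1.79 ± 0.15, quantile 2.75), SYN1 (1.80 ± 0.17, quantile 2.65) and SYT1 (1.33 ± 0.14, quantile 2.13), while the neuronal DPYSL3 (-1.21 ± 0.14, quantile -0.17) fell in deposited values.

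Signalling, proliferation and repair genes fell. RAF-MEK-ERK output had 22 of 23 genes lower (median -1.86, quantile -0.91), including DUSP4 (-2.96 ± 0.16, quantile -1.98), DUSP6 (-2.74 ± 0.13, quantile -1.68) and FOSL1 (-2.65 ± 0.14, quantile -1.64). Ribosome biogenesis had 26 of 26 (median -1.91, quantile -0.88), including MRTO4 (-2.33 ± 0.14, quantile -1.29), NOB1 (-2.28 ± 0.14, quantile -1.18), LYAR (-2.32 ± 0.14, quantile -1.25) and NOP16 (-2.22 ± 0.14, quantile -1.14). Replication had 19 of 19 (median -2.01, quantile -0.94), including GINS2 (-2.67 ± 0.15, quantile -1.68), MCM3 (-2.36 ± 0.14, quantile -1.27), TYMS (-2.23 ± 0.13, quantile -1.23) and FEN1 (-2.18 ± 0.14, quantile -1.12). Mitosis had 29 of 29 (median -1.45, quantile -0.51), including MAD2L1 (-2.38 ± 0.14, quantile -1.44), NDC80 (-2.24 ± 0.14, quantile -1.25) and PLK1 (-1.72 ± 0.13, quantile -0.64). Adjusted over the list alone these 4 counts were 22, 26, 19 and 29. Camera adjusted p was 3.6e-07, 4.2e-10, 3.1e-08 and 5.7e-08, and adjusted p = 0.58 with an estimated correlation for each. In quantile-normalized values the 4 lists had 19, 25, 17 and 23 falls. Their adjusted p values there were 0.0041, 0.0012, 0.0078 and 0.08 with an estimated correlation. G1 control had 17 of 18 genes lower (17 adjusted over the list alone) and the damage checkpoint 14 of 14 genes lower (14 adjusted over the list alone) (camera adjusted p = 1.1e-04 and 4.9e-04, and adjusted p = 0.58 and 0.58 with an estimated correlation). The falls numbered 13 and 9 after quantile normalization (adjusted p = 0.0075 and 0.12 with an estimated correlation).

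Among repair lists, homologous recombination had 23 of 24 genes lower (23 adjusted over the list alone), with 16 falls and 2 rises after quantile normalization (adjusted p = 8.8e-05, and adjusted p = 0.026 with an estimated correlation). Examples were PALB2 (-1.99 ± 0.14, quantile -0.97), RAD51AP1 (-2.18 ± 0.14, quantile -1.66), TOP3A (-2.03 ± 0.14, quantile -1.04) and XRCC2 (-2.09 ± 0.16, quantile -1.02). In end joining 9 of 10 fell (9 adjusted over the list alone), and 8 fell and 1 rose after quantile normalization (adjusted p = 0.026, and adjusted p = 0.088 with an estimated correlation). These included Artemis, DCLRE1C (-2.08 ± 0.17, quantile -1.29), XRCC4 (-1.61 ± 0.13, quantile -0.51), XRCC1 (-1.88 ± 0.15, quantile -0.80) and PARP1 (-1.42 ± 0.14, quantile -0.36). XRCC4 stood at 203 ± 22.9 in DMSO, 194 ± 12 in DT, 188 ± 3.22 in E and 66.2 ± 1.31 in DTE (SD, n = 3). Base excision repair had 17 of 17 genes lower (17 adjusted over the list alone), and 13 after quantile normalization (adjusted p = 3.5e-05, and adjusted p = 0.008 with an estimated correlation), with UNG (-2.57 ± 0.15, quantile -1.52), PARP2 (-1.97 ± 0.15, quantile -0.90) and NTHL1 (-1.83 ± 0.15, quantile -0.73). In deposited values the adjusted p with an estimated correlation was 0.58 for each of the 3 lists, against preset-correlation values of 2.3e-05, 0.011 and 5.6e-05. Melanocyte genes had 14 of 17 genes lower (14 adjusted over the list alone) (camera adjusted p = 0.013, and adjusted p = 0.58 with an estimated correlation). They included MITF (-2.19 ± 0.15, quantile -1.10), MLANA (-2.09 ± 0.15, quantile -1.01) and the endothelin receptor EDNRB (-1.85 ± 0.14, quantile -0.75). The list had 10 falls after quantile normalization (adjusted p = 0.0088, and adjusted p = 0.12 with an estimated correlation).

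Some deposited falls went with the lower level of the DTE arrays. Housekeeping had 12 of 12 genes lower (12 adjusted over the list alone) in deposited values (median -1.15, camera adjusted p = 0.0027, and adjusted p = 0.58 with an estimated correlation) and 1 after quantile normalization (median -0.09, adjusted p = 0.47). Ribosomal proteins had 20 of 20 genes lower (20 adjusted over the list alone) in deposited values (median -1.08, camera adjusted p = 4.9e-04, and adjusted p = 0.58 with an estimated correlation) and 3 after it (adjusted p = 0.21). Receptor kinases had 6 of 20 genes higher (6 adjusted over the list alone) and 8 lower. Their median of -0.16 and mean of -0.21 lay below 0 while camera called them upward relative to other genes (camera adjusted p = 0.011, and adjusted p = 0.58 with an estimated correlation). There were 13 rises and 3 falls after quantile normalization (adjusted p = 0.004, and adjusted p = 0.08 with an estimated correlation). ERBB3 (-1.82 ± 0.14, quantile -0.78), EPHA2 (-1.50 ± 0.14, quantile -0.45), DDR2 (-1.40 ± 0.14, quantile -0.31) and AXL (-1.29 ± 0.13, quantile -0.22) fell in deposited values. Genes known to rise with class I inhibitors had 2 of 11 genes higher (2 adjusted over the list alone) and 6 lower. Their median of -0.43 and mean of -0.15 also lay below 0 with an upward call (camera adjusted p = 0.044, and adjusted p = 0.58 with an estimated correlation), lost when any 1 of 4 of the arrays was left out. The list had 5 rises after quantile normalization (adjusted p = 0.0046, and adjusted p = 0.088 with an estimated correlation). HDAC1 (-0.79 ± 0.15, quantile 0.30) and HDAC3 (-0.59 ± 0.14, quantile 0.50) fell in deposited values and rose after quantile normalization, and HDAC2 (-0.61 ± 0.16, quantile 0.19), MAP2K1 (-1.01 ± 0.14, quantile 0.09) and MAP2K2 (-0.54 ± 0.18, quantile 0.27) fell in deposited values and turned positive, short of the threshold, after it. BCL2L11 (-0.15 ± 0.15, quantile 0.92) changed sign and rose only after quantile normalization (adjusted p = 8.1e-07). MYC (-2.83 ± 0.17, quantile -1.85), ETV5 (-2.48 ± 0.15, quantile -1.44), CCND1 (-1.94 ± 0.14, quantile -0.86) and XRCC5 (-1.18 ± 0.13, quantile -0.23) fell in both, and MGMT (-0.73 ± 0.15, quantile -0.16) fell in deposited values alone. Between DTE and DMSO, 9490 of 14582 genes passed limma's moderated test in deposited values, 621 higher and 8869 lower, of which 117 and 4001 differed at least 2-fold. After quantile normalization 2989 were higher and 3272 lower, with 546 and 316 at least 2-fold, and 40.7% of the deposited calls were called again in the same direction.

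**Figure D3:**
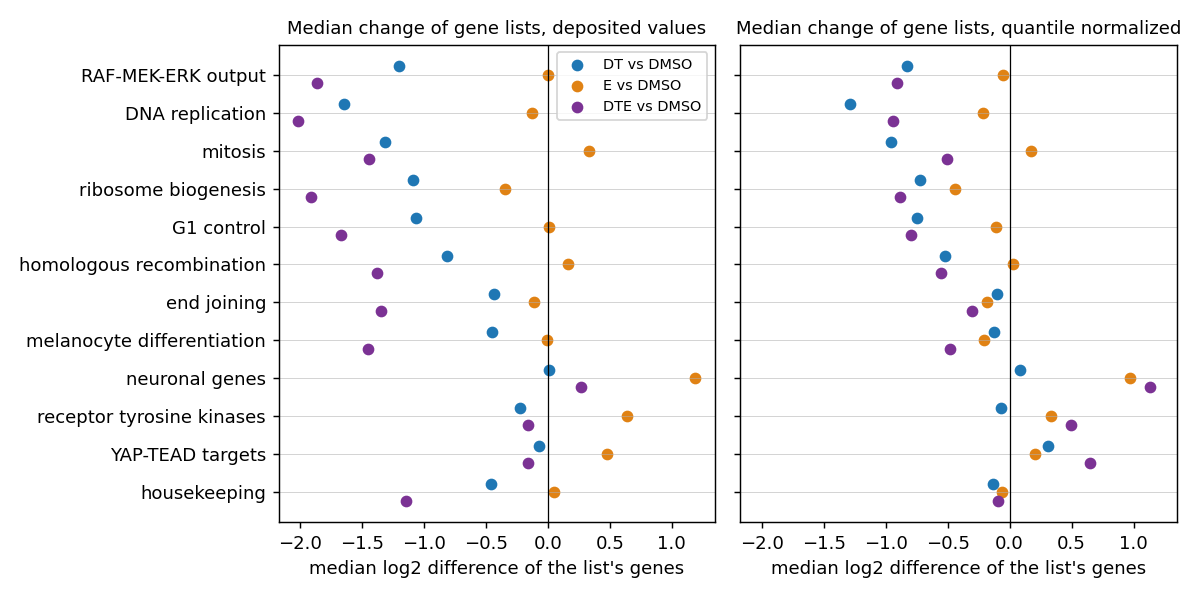
Median log2 difference against DMSO of the measured genes of 12 lists (rows) for DT, E and DTE (colours), from deposited values (left) and after quantile normalization (right). Housekeeping genes in DTE lie at -1.15 on the left and -0.09 on the right, and the neuronal list in DTE at 0.27 and 1.13, while receptor kinases in DTE, YAP-TEAD targets in DT and DTE, and RAF-MEK-ERK output, G1 control and housekeeping in E change sign between the panels.

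Adding entinostat to dabrafenib plus trametinib raised STC1 (at least 12.3-fold, quantile at least 20.2-fold), TSPAN13 (3.19 ± 0.16, quantile 3.90), EBLN1 (at least 3.45-fold, quantile at least 5.54-fold), KIF5C (2.35 ± 0.16, quantile 3.07), the calsyntenin CLSTN3 (2.30 ± 0.23, quantile 3.03) and COXFA4L3 (2.29 ± 0.15, quantile 2.98). It lowered several genes that dabrafenib plus trametinib alone had raised: ANGPTL7 (-4.26 ± 0.18, quantile -3.54), AQP7P1 (-3.82 ± 0.17, quantile -3.37) and MAP1LC3C (-3.27 ± 0.14, quantile -3.02), as well as TRIM48 (-4.04 ± 0.20, quantile -3.71), KRTAP21-1 (-3.16 ± 0.17, quantile -2.75) and the neural crest factor FOXD3 (-3.02 ± 0.15, quantile -2.69). In the neuronal list 10 of 28 rose (10 adjusted over the list alone) and 3 fell (camera adjusted p = 3.0e-13, and adjusted p = 0.43 with an estimated correlation). Among those that rose were SYN1 (2.27 ± 0.17, quantile 2.98), SCG3 (at least 1.25-fold, quantile at least 1.55-fold), CALB2 (1.00 ± 0.13, quantile 1.69) and MAP2 (0.98 ± 0.15, quantile 1.67). After quantile normalization 20 rose and 0 fell (adjusted p = 1.0e-11, and adjusted p = 0.0013 with an estimated correlation). Receptor kinases had 7 of 20 genes higher (7 adjusted over the list alone) and 4 lower, a median of -0.03, a mean of 0.02 and an upward call relative to other genes (camera adjusted p = 1.7e-04, and adjusted p = 0.98 with an estimated correlation). The quantile counts were 13 and 2 (adjusted p = 8.1e-05, and adjusted p = 0.092 with an estimated correlation). There were rises of ERBB4 (at least 2.32-fold, quantile at least 3.47-fold) and FGFR1 (at least 1.76-fold, quantile at least 2.43-fold) and falls of ERBB3 (-2.02 ± 0.14, quantile -1.28) and DDR2 (-1.86 ± 0.14, quantile -1.10).

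End-joining genes had 8 of 10 genes lower (8 adjusted over the list alone) (camera adjusted p = 0.045, and adjusted p = 0.98 with an estimated correlation), a call lost without E replicate 1 or DTE replicate 2. They included XRCC4 (-1.55 ± 0.13, quantile -0.82), DCLRE1C (-1.33 ± 0.17, quantile -0.88), TP53BP1 (-1.30 ± 0.15, quantile -0.61) and PARP1 (-1.01 ± 0.14, quantile -0.30). There were 5 falls and 1 rise after quantile normalization (adjusted p = 0.19). Base excision repair had 16 of 17 genes lower (16 adjusted over the list alone) (camera adjusted p = 0.023, and adjusted p = 0.98 with an estimated correlation). They included NEIL1 (-1.46 ± 0.14, quantile -1.07), UNG (-1.21 ± 0.15, quantile -0.53) and APEX1 (-1.07 ± 0.15, quantile -0.39). There were 8 falls and 1 rise after it (adjusted p = 0.18). Replication and mitosis genes changed direction with the scaling. In deposited values mitosis had 11 of 29 genes lower (9 adjusted over the list alone) and replication 10 of 19 genes lower (10 adjusted over the list alone), and 1 of each rose, while camera pointed upward relative to other genes without a call (adjusted p = 0.089 and 0.63). After quantile normalization mitosis had 18 of 29 genes higher (18 adjusted over the list alone) and replication 10 of 19 genes higher (10 adjusted over the list alone), and 1 of each fell. Those quantile calls had adjusted p values of 5.0e-07 and 8.1e-05, and adjusted p = 0.092 and 0.092 with an estimated correlation. Ribosome biogenesis had 25 of 26 genes lower (26 adjusted over the list alone) (camera adjusted p = 0.0076, and adjusted p = 0.98 with an estimated correlation). After quantile normalization it had 5 falls and 4 rises, a median of 0.05 and a mean of -0.04 (adjusted p = 0.94). Histone deacetylases and sirtuins had 16 of 18 genes lower (16 adjusted over the list alone) (camera adjusted p = 0.031, and adjusted p = 0.98 with an estimated correlation), and 5 falls and 4 rises after it (adjusted p = 0.39). Of the 17 genes named in advance and measured, 12 fell and 0 rose in deposited values, and 4 fell and 8 rose after quantile normalization. DUSP6 (-1.62 ± 0.13, quantile -0.90), XRCC4, MLANA (-1.14 ± 0.15, quantile -0.43) and MGMT (-0.70 ± 0.15, quantile -0.31) fell in both, while MITF (-0.09 ± 0.15, quantile 0.63) and BCL2L11 (-0.02 ± 0.15, quantile 0.70) changed sign and rose after quantile normalization, as did HDAC1, HDAC2, HDAC3, MAP2K1, DUSP4 and MYC. Between DTE and DT, 8466 of 14582 genes passed limma's moderated test in deposited values, 597 higher and 7869 lower, of which 112 and 1449 differed at least 2-fold. After quantile normalization 2386 were higher and 2607 lower, with 414 and 169 at least 2-fold, and 37.7% of the deposited calls were called again in the same direction.

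Adding dabrafenib plus trametinib to entinostat lowered UCN2 (-5.31 ± 0.17, quantile -4.31), SPRY4 (-4.16 ± 0.17, quantile -3.12), ZNF114 (-3.91 ± 0.16, quantile -2.96), the signalling regulator RGS1 (at least 10.8-fold, quantile at least 6.87-fold), DUSP4 (-3.01 ± 0.16, quantile -1.96) and DUSP6 (-3.00 ± 0.13, quantile -1.86). It raised ANGPTL7 (1.99 ± 0.18, quantile 3.13), PDZRN3 (0.96 ± 0.15, quantile 2.08), LCTL (0.77 ± 0.13, quantile 1.87), PRUNE2 (0.67 ± 0.16, quantile 1.68), JAKMIP2 (0.56 ± 0.14, quantile 1.69) and CCN3 (0.38 ± 0.13, quantile 1.46). All 23 RAF-MEK-ERK output genes fell (median -1.60), as did all 29 mitosis genes (-1.80) and all 19 replication genes (-1.93). All 26 ribosome biogenesis genes (-1.47) and all 24 homologous recombination genes (-1.71) fell as well, and adjusted over the list alone these 5 counts were 23, 29, 19, 26 and 24. Camera adjusted p was 6.0e-08, 3.3e-11, 2.7e-09, 1.6e-07 and 5.6e-07, and adjusted p = 0.68 with an estimated correlation for each. After quantile normalization 18, 26, 17, 19 and 16 members fell, with medians of -0.51, -0.68, -0.77, -0.36 and -0.58. The adjusted p values there were 0.0011, 0.0033, 0.0012, 0.0011 and 0.0026 with an estimated correlation. Examples were FOSL1 (-2.58 ± 0.14, quantile -1.50), MAD2L1 (-2.57 ± 0.14, quantile -1.52), CCNB1 (-2.05 ± 0.13, quantile -0.92), GINS2 (-2.44 ± 0.15, quantile -1.38), CDC6 (-2.10 ± 0.14, quantile -1.01), LYAR (-2.17 ± 0.14, quantile -1.02), EXO1 (-2.24 ± 0.15, quantile -1.23) and RAD51C (-1.74 ± 0.13, quantile -0.58).

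In deposited values G1 control had 18 of 18 genes lower (18 adjusted over the list alone), the damage checkpoint 14 of 14 genes lower (14 adjusted over the list alone) and end joining 10 of 10 genes lower (10 adjusted over the list alone). Camera adjusted p was 2.9e-05, 6.7e-05 and 0.0052, and adjusted p = 0.68, 0.68 and 0.68 with an estimated correlation. G1 control had 13 falls after quantile normalization (adjusted p = 1.5e-09, and adjusted p = 0.0012 with an estimated correlation), the damage checkpoint 9 (adjusted p = 7.2e-07, and adjusted p = 0.029 with an estimated correlation) and end joining 3 (adjusted p = 0.0044, and adjusted p = 0.042 with an estimated correlation). Melanocyte genes had 16 of 17 genes lower (16 adjusted over the list alone) (camera adjusted p = 0.02, and adjusted p = 0.75 with an estimated correlation). They included MITF (-1.80 ± 0.15, quantile -0.64), PMEL (-1.97 ± 0.15, quantile -0.86) and EDNRB (-1.93 ± 0.14, quantile -0.76). The list had 9 falls and 2 rises after quantile normalization (adjusted p = 0.0014, and adjusted p = 0.084 with an estimated correlation). Cytokines and NF-kB targets were called after quantile normalization alone, with 5 of 18 genes lower (5 adjusted over the list alone) (adjusted p = 0.033, and adjusted p = 0.19 with an estimated correlation). Among them were ICAM1 (-2.36 ± 0.16, quantile -1.22), CXCL8 (at least 1.6-fold, quantile at least 1.14-fold) and IL11 (-1.72 ± 0.16, quantile -0.72). The neuronal list turned with the scaling: it had 23 of 28 genes lower (23 adjusted over the list alone) in deposited values, with a median of -0.76 while camera pointed upward relative to other genes without a call (adjusted p = 0.63). There were 8 rises against 2 falls after quantile normalization (adjusted p = 0.011, and adjusted p = 0.045 with an estimated correlation). Of the genes named in advance, 17 of 17 fell in deposited values. After quantile normalization 10 fell and 1 rose, the latter being BCL2L11 (-0.76 ± 0.15, quantile 0.42). Between DTE and E, 11489 of 14582 genes passed limma's moderated test in deposited values, 36 higher and 11453 lower, of which 2 and 5229 differed at least 2-fold. After quantile normalization 1466 were higher and 1457 lower, with 64 and 99 at least 2-fold, and 13% of the deposited calls were called again in the same direction.

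The interaction compares the effect of entinostat in the presence of dabrafenib plus trametinib with its effect alone, and is 0 where effects add on the log2 scale. Among genes that met the naming rule, the lowest values belonged to AQP7P1 (-4.13 ± 0.24, quantile -3.39), KRTAP21-1 (-3.24 ± 0.24, quantile -2.63), MAP1LC3C (-3.03 ± 0.20, quantile -2.55), JUN (-2.77 ± 0.19, quantile -1.97), ANGPTL7 (-2.62 ± 0.26, quantile -1.82) and FHDC1 (-2.51 ± 0.22, quantile -1.54). JUN stood at 115 ± 14.2 in DMSO, 523 ± 40.1 in DT, 222 ± 17.1 in E and 148 ± 9.74 in DTE (SD, n = 3), and ANGPTL7 at 107 ± 9.19, 2601 ± 178, 35.3 ± 10.1 and 138 ± 29.9. Among the same genes, the highest values belonged to ANKS1A (1.29 ± 0.23, quantile 2.12), MYC (1.10 ± 0.24, quantile 1.78), PRR7-AS1 (0.96 ± 0.23, quantile 1.43), SLCO4A1-AS1 (0.75 ± 0.25, quantile 1.38), PRDM7 (0.71 ± 0.30, quantile 1.01) and LPXN (0.69 ± 0.22, quantile 1.39). Of these, PRDM7 lost the call after quantile normalization (adjusted p = 0.066). It lay near background in DTE at 12.8 ± 3.8 (SD, n = 3). Additive MYC, PRR7-AS1 and SLCO4A1-AS1 levels would too. None of these can be told from compression. MYC stood at 245 ± 41.6, 41.1 ± 6.07, 96.2 ± 18.5 and 34.4 ± 4.94 in the same order. Of the genes named in advance, DUSP6 (-1.89 ± 0.19, quantile -1.08) and XRCC4 (-1.45 ± 0.18, quantile -0.64) were lower than additive under both scalings, MYC higher under both, and MITF (0.29 ± 0.21, quantile 1.09) was higher than additive after quantile normalization (adjusted p = 2.3e-04). In deposited values 12 of the 17 were lower and 1 higher than additive, and 2 and 2 after quantile normalization.

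**Figure D4:**
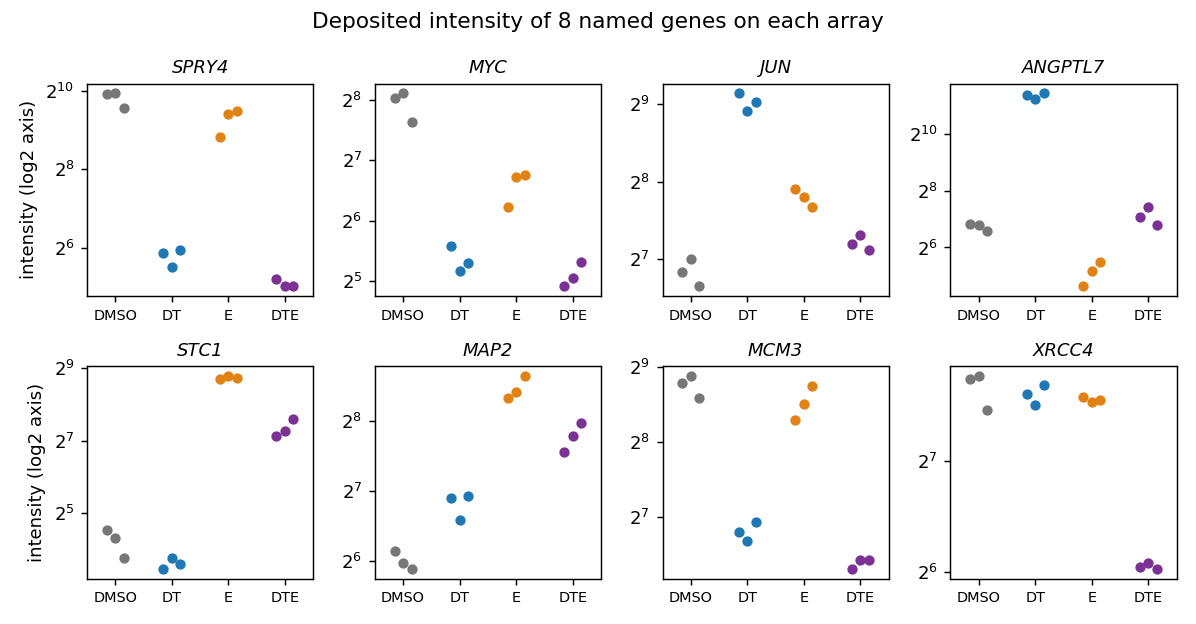
Deposited intensity (log2 axis, arbitrary units) of 8 genes on each of the 12 arrays, by treatment group. JUN and ANGPTL7 are highest on the 3 DT arrays, STC1 and MAP2 on the 3 E arrays, and XRCC4 is lowest on the 3 DTE arrays.

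Proliferation lists lay above additivity after quantile normalization. There ribosome biogenesis had 9 of 26 genes higher (18 adjusted over the list alone) (median 0.42, adjusted p = 7.6e-13, and adjusted p = 0.001 with an estimated correlation) and replication 11 of 19 genes higher (15 adjusted over the list alone) (median 0.52, adjusted p = 5.5e-12, and adjusted p = 0.008 with an estimated correlation). Mitosis had 5 of 29 genes higher (9 adjusted over the list alone) (adjusted p = 2.3e-05, and adjusted p = 0.12 with an estimated correlation) and G1 control 2 of 18 genes higher (5 adjusted over the list alone) (adjusted p = 0.0029, and adjusted p = 0.047 with an estimated correlation). RAF-MEK-ERK output had 4 of 23 genes higher (7 adjusted over the list alone) and 2 lower (adjusted p = 0.019, and adjusted p = 0.12 with an estimated correlation). In deposited values the medians and means of these 5 lists lay below 0 while camera put them above other genes, with medians at -0.37, -0.23, -0.46, -0.54 and -0.53. Of these 5 lists replication alone was called there (camera adjusted p = 0.021, and adjusted p = 0.99 with an estimated correlation), a call lost without DMSO replicate 2, DT replicate 2 or E replicate 1. Histone deacetylases and sirtuins lay below other genes, with 16 of 18 genes lower (17 adjusted over the list alone) (camera adjusted p = 0.014, and adjusted p = 0.99 with an estimated correlation) and 2 after quantile normalization (adjusted p = 0.03, and adjusted p = 0.22 with an estimated correlation). For the interaction, 9147 of 14582 genes passed limma's moderated test in deposited values, 30 higher and 9117 lower, of which 3 and 1923 differed at least 2-fold. After quantile normalization 303 were higher and 309 lower, with 35 and 52 at least 2-fold, and 3.6% of the deposited calls were called again in the same direction. Among the deposited calls, 8807 of the lower ones were not called after quantile normalization.

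The response to each treatment was compared with and without the other across 14582 genes, which are not independent replicates. The change with dabrafenib plus trametinib alone and its change on top of entinostat, which share no arrays, correlated at Pearson's r = 0.66 (Spearman's rho 0.66), and at 0.70 (0.59) after quantile normalization. After quantile normalization 999 genes rose in both, against 221 for independent lists, and 1061 fell in both, against 213. For entinostat alone and on top of dabrafenib plus trametinib, r was 0.66 (rho 0.52) and 0.78 (0.67) after quantile normalization, where 1555 genes rose in both against 360 for independent lists and 1468 fell in both against 426. The changes with dabrafenib plus trametinib and with entinostat, which share the DMSO arrays, correlated at r = 0.23, below the 0.50 that unchanged groups against the same controls gave in simulation. Their covariance was 0.0446 against a simulated 0.0118, and 0.028 against 0.00727 after quantile normalization. In quantile-normalized values 672 genes rose in both against 332 for independent lists, and 794 fell in both against 348. The 3 DMSO arrays were not split, since 1 part would hold a single array, so part of the excess may come from the shared controls.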

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

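Tests chosen only after the result was seen were that of a constant factor per array, that of an additive background without genes near background, that of level variation within groups, the share of interaction calls kept after quantile normalization, the regroupings of residuals, the subtraction of the fitted background, the filter on DMSO alone, and the matched gene sets for ribosome biogenesis alone.

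The difference between the entinostat effects with and without dabrafenib plus trametinib passed the interaction test for 9147 genes in deposited values, 1926 of them at least 2-fold. Among the genes named here, the interaction passed with values below 0 for BCL2L11 (-0.63, quantile 0.19), CCND1 (-0.57, quantile 0.21), HDAC1 (-0.98, quantile -0.15), HDAC2 (-0.62, quantile 0.21), HDAC3 (-0.89, quantile -0.07), MAP2K1 (-0.88, quantile -0.08), MAP2K2 (-0.86, quantile -0.02), MGMT (-0.83, quantile -0.17), MLANA (-0.61, quantile 0.19), XRCC4 (-1.45, quantile -0.64), XRCC5 (-0.61, quantile 0.10) and DUSP6 (-1.89, quantile -1.08). The values of BCL2L11, CCND1, HDAC2, MLANA and XRCC5 turned positive after quantile normalization. The lowest were ANGPTL7 (-2.62, quantile -1.82), AQP7P1 (-4.13, quantile -3.39), FHDC1 (-2.51, quantile -1.54), JUN (-2.77, quantile -1.97), KRTAP21-1 (-3.24, quantile -2.63) and MAP1LC3C (-3.03, quantile -2.55). Values above 0 were those of MYC (1.10, quantile 1.78), ANKS1A (1.29, quantile 2.12), LPXN (0.69, quantile 1.39), PRDM7 (0.71, quantile 1.01), PRR7-AS1 (0.96, quantile 1.43) and SLCO4A1-AS1 (0.75, quantile 1.38). PRDM7, MYC, PRR7-AS1 and SLCO4A1-AS1 cannot be told from compression near background. Lists called in the interaction were replication (median minus that of all genes 0.39), metallothioneins (0.35, with a median of -0.27 itself), histone deacetylases and sirtuins (-0.34), lysosome and autophagy (-0.24) and sterol synthesis (-0.34), each with adjusted p = 0.99 with an estimated correlation. The call of replication was lost when any 1 of 3 of the arrays was left out, and that of sterol synthesis with any 1 of 5. After quantile normalization the medians were 0.52 (adjusted p = 5.5e-12, and adjusted p = 0.008 with an estimated correlation) for replication and -0.15 (adjusted p = 0.03, and adjusted p = 0.22 with an estimated correlation) for histone deacetylases and sirtuins, while no call was left for metallothioneins, 0.10 (adjusted p = 0.22, and adjusted p = 0.33 with an estimated correlation), lysosome and autophagy, -0.09 (adjusted p = 0.36, and adjusted p = 0.44 with an estimated correlation), and sterol synthesis, -0.15 (adjusted p = 0.22, and adjusted p = 0.42 with an estimated correlation). Of the probe sets not named here, which no comparison uses, those at least 2-fold higher and lower were 115 and 373 in DT against DMSO, 469 and 75 in E against DMSO and 149 and 2306 in DTE against DMSO. After quantile normalization they were 195 and 167 (362 in all), 261 and 100 (361), and 456 and 228 (684).

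The first pattern is the lower level of most genes on the DTE arrays. One constant factor per array is argued against by the shift of the brightest minus that of the dimmest of 15 bins of intensity above background, -0.93 on the log2 scale (-0.98 to -0.83 with 1 array left out), and level variation of the size seen within groups is argued against by the distance of the DTE arrays from the others (exact p = 0.018 over 15400 partitions of the arrays, while DTE against DMSO alone gave 0.1, each the smallest possible). A factor above an additive background stays open, in these bins and over all bins. Its largest residual over these bins was 0.12 (0.086 to 0.13, with 1 array left out), which is not within 0.1 in each fit, as this explanation needs, nor above 0.2, which would argue against it. The same test over all 20 bins, with these bounds written before it was run, left 0.41. That value, in the dimmest bin at an intensity of 4.11, passed the bound of 0.2. In that fit bins above background passed it too, at up to 0.25. Over all bins this argues against the explanation. Handling shared by the arrays of 1 group was not tested and stays open. Less RNA per unit of spike-in stays open, since 0 probe sets are named for ERCC controls here. An effect of the treatments on the RNA content of the cells also stays open and was not tested.

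The second pattern is that interaction calls in deposited values were nearly all below 0. A difference in level between the arrays and a response of the cells shared by most genes cannot be told apart here. The share called in the same direction after quantile normalization, 3.6%, does not decide, since that step removes a shared shift whatever its cause. A smaller set stays open as a response of the cells to the combination, with a direction that depends on the scaling: 303 genes above and 309 below additivity after quantile normalization, and 1872 above and 668 below after median centring. With both treatment effects kept, only the real split of 100 residual splits called as many as 9147 genes. Others called a median of 0 and up to 6533 on residuals still holding the interaction. Chance is argued against but not excluded, with 100 splits and a test chosen afterwards. The test does not separate a cell response from array levels.

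The third pattern is that replication, mitosis and ribosome biogenesis genes lay above additivity after quantile normalization. Compression near the background is argued against only for the 57 members well above it in every group. They kept a median of 0.46 above other genes as far above it after its subtraction (0.45 to 0.49 with 1 array left out), and 0.50 (0.47 to 0.52) after subtraction of the fitted background of 12. That filter uses the DTE level itself and can leave out members that fell furthest there. With a filter on DMSO alone the values were 0.45 (0.43 to 0.49) and 0.55 (0.50 to 0.56). That filter kept all 74 measured members, also those near background in DTE, such as WDR74 at 12.8. It therefore cannot decide on compression. Genes matched on level and on their fall with dabrafenib plus trametinib had a median of 0.33 against 0.39 for the 3 lists, which lay at percentile 95.2 of matched sets, so the pattern may be shared by any gene that fell as far. Ribosome biogenesis alone lay at percentile 98.9, above the central range, replication at 79.4 and mitosis at 39.7. Matched genes were drawn independently of each other, while genes of a list can vary together, so these percentiles may be too extreme. They are not adjusted for the 3 lists looked at. A biological difference for ribosome biogenesis is a hypothesis found on the same data.

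Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05, and in each the real split was the only 1 to call as many genes. The real splits called 4056 genes for DT against DMSO, 3734 for E against DMSO, 9490 for DTE against DMSO, 8466 for DTE against DT and 11489 for DTE against E, and the highest other split called 0 in each.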

How the results depend on the processing

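Chosen after the data were seen were quantile normalization of lists, genes and correlations, median centring of genes, and centring on the brighter part of the genes; the other alternatives were planned. Signal over background limits dim genes, and 3 arrays per group limit all tests. The shift to equal spike-in levels was not run, since no probe set is named for ERCC controls here. The cause was not tested for any change below unless one is named.

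Leaving out each array gave these ranges of genes changed: 3002 to 4688 for DT against DMSO, 2927 to 4296 for E against DMSO, 8647 to 9764 for DTE against DMSO, 7252 to 8816 for DTE against DT, 10807 to 11723 for DTE against E and 7714 to 10207 for the interaction. At least 2-fold the ranges were 655 to 924, 631 to 821, 3745 to 4780, 1391 to 1936, 4126 to 6411 and 1294 to 3068 in the same order, the last reaching 3068 without E replicate 1. Quantile normalization gave 6261, 4993, 2923 and 612 genes changed for the last 4 comparisons, and 448, 449, 862, 583, 163 and 87 at least 2-fold for all 6. Centring on the brighter genes, which tests fewer genes, gave 4837, 3799, 3069 and 1164 for the last 4, and 424, 354, 629, 356, 108 and 68 at least 2-fold. Median centring gave 2540 for the interaction, and 1442, 624, 562 and 207 at least 2-fold for the last 4. Leaving out the dimmer genes, which tests fewer, gave 2365 for E against DMSO (398 at least 2-fold) and 7209 for DTE against E. The direction of calls also moved. Median centring gave 2286 higher and 2575 lower for DT against DMSO; 1699 higher and 3813 lower for E against DMSO; 5518 higher and 4624 lower for DTE against DMSO; 3519 higher and 3737 lower for DTE against DT; 5274 higher and 2812 lower for DTE against E; 1872 higher and 668 lower for the interaction. Centring on the brighter genes gave 2298 and 1842; 1856 and 2138; 2627 and 2210; 1965 and 1834; 1896 and 1173; 654 and 510 in the same order. For E against DMSO the lower calls ranged from 411 to 933 and the higher ones from 2175 to 3867 with 1 array left out. Array weights, whose estimation did not fully converge, gave 7226 for E against DMSO.

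Correlations of the same treatment in both backgrounds moved to 0.79 (dabrafenib plus trametinib) and 0.80 (entinostat) without the dimmer genes, and to 0.78 (entinostat) after quantile normalization. With a replicate block the genes changed were 3749, 3387, 9283, 8197, 11393 and 8738, counts at least 2-fold were equal, and of the named genes only HDAC2 lost its call, in DT and in E. Arrays of the same number correlated from -0.22 to 0.13 after removal of group means, with 2 of 18 pairs above 0.1. Their mean was -0.02, against 0.01 for arrays of other numbers. No pairing by number was seen, which does not exclude that arrays of 1 number were handled together.

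Reversals are listed where the value passed the threshold before or after. Signs of named genes reversed after quantile normalization, where the level shift is removed: BCL2L11 0.23 and XRCC4 0.31 in DT against DMSO; BCL2L11 0.92, HDAC1 0.30, HDAC2 0.19, HDAC3 0.50, MAP2K1 0.094 and MAP2K2 0.27 in DTE against DMSO; BCL2L11 0.70, CCND1 0.16, DUSP4 0.34, ETV5 0.17, HDAC1 0.26, HDAC2 0.40, HDAC3 0.36, MAP2K1 0.37, MITF 0.63 and MYC 0.33 in DTE against DT; BCL2L11 0.42, HDAC3 0.066 and MAP2K2 0.32 in DTE against E; BCL2L11 0.19, CCND1 0.21, HDAC2 0.21, MLANA 0.19 and XRCC5 0.095 in the interaction. Median centring reversed CCND1 -0.28 in E against DMSO; BCL2L11 0.49, HDAC2 0.036, HDAC3 0.053 and MAP2K2 0.10 in DTE against DMSO; BCL2L11 0.42, HDAC2 0.29, HDAC3 0.073, MAP2K1 0.092 and MITF 0.35 in DTE against DT; BCL2L11 0.17, MAP2K2 0.18 and MGMT 0.067 in DTE against E; BCL2L11 0.10, CCND1 0.16, HDAC2 0.11, MLANA 0.12, SPRY4 0.61 and XRCC5 0.12 in the interaction. Fry, which tests a list without comparing it with other genes, gave a direction opposite to camera's for these of the lists run under alternatives, called by at least 1 of the tests, with means of: cancer-testis genes -0.34, inhibitor-induced genes -0.15, interferon-stimulated genes -0.48, keratinocyte markers -0.19 and receptor kinases -0.21 in DTE against DMSO; replication -0.30 and receptor kinases 0.025 in DTE against DT; the neuronal list -0.72 in DTE against E; G1 control -0.49, replication -0.29, RAF-MEK-ERK output -0.50, metallothioneins -0.20, mitosis -0.50 and ribosome biogenesis -0.38 in the interaction. The receptor kinase mean in DTE against DT has camera's sign, while fry's direction, far from its threshold, was downward. Ribosome biogenesis in DTE against DT, measured against other genes, was 0.080 after quantile normalization.

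Of 3936 values of named genes with an array left out, 49 lost and 8 gained the call, and 0 reversed. Of 996 of lists, 17 lost and 6 gained it. The losses were interferon-stimulated genes in DT against DMSO (without DMSO replicate 2 or 3, or DT replicate 2), inhibitor-induced genes in DTE against DMSO (DMSO replicate 1 or 3, DTE replicate 2 or 3), end joining in DTE against DT (E replicate 1 or DTE replicate 2), replication in the interaction (DMSO replicate 2, DT replicate 2 or E replicate 1) and sterol synthesis in the interaction (DMSO replicate 1, DT replicate 1 or 2, E replicate 2 or DTE replicate 3). With an estimated correlation all 49 called results among the 83 described for lists lost the call, and the others had none.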

Other observations

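The lists below were fixed before the data were examined and were picked for description after their values were seen, and none of the tests of response ratios was chosen after its result, though the one for genes lowered by entinostat was read anew after it. Camera compares a list with other genes and fry does not.

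Interferon-stimulated genes were called upward by camera in DT against DMSO, a call lost when any 1 of 3 of the arrays was left out, with 3 higher and 3 lower of 29 (adjusted over the list alone 2 and 2, quantile 10 and 1), a median of 0.02 and camera adjusted p = 0.037, and adjusted p = 0.71 with an estimated correlation. After quantile normalization the median was 0.13 (adjusted p = 0.039, and adjusted p = 0.18 with an estimated correlation). In E against DMSO the counts were 10 higher and 1 lower of 29 (adjusted over the list alone 13 and 1, quantile 8 and 4) (adjusted p = 0.2) and in DTE against DMSO 0 higher and 18 lower of 29 (adjusted over the list alone 0 and 18, quantile 10 and 3), with a median of -0.50 and 0.08 in quantile-normalized values (adjusted p = 0.59), where camera pointed upward relative to other genes in both. Camera made no call for p53 targets, with 2 higher and 6 lower of 14 (adjusted over the list alone 2 and 7, quantile 3 and 5) in DT, 5 higher and 0 lower of 14 (adjusted over the list alone 5 and 0, quantile 3 and 1) in E and 1 higher and 9 lower of 14 (adjusted over the list alone 1 and 9, quantile 2 and 4) in DTE (adjusted p = 0.49, 0.37 and 0.56). Fry called them downward in DT (adjusted p = 0.025), upward in E (0.015) and downward in DTE (3.0e-05), and in none after quantile normalization. The BCL2 family had 1 higher and 4 lower of 14 (adjusted over the list alone 1 and 7, quantile 2 and 2) in DT, 2 higher and 0 lower of 14 (adjusted over the list alone 2 and 0, quantile 2 and 1) in E and 0 higher and 11 lower of 14 (adjusted over the list alone 0 and 11, quantile 3 and 4) in DTE (adjusted p = 0.41, 0.77 and 0.23), with a downward call by fry in DTE (1.2e-04, quantile 0.75). Cancer-testis genes had 2 higher and 1 lower of 8 (adjusted over the list alone 2 and 1, quantile 1 and 1) in E (adjusted p = 0.89).

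Markers of cell types other than melanoma cells were not called by camera in any comparison with DMSO. With entinostat, immune markers, which include CSF1R, had 3 higher and 0 lower of 6 (adjusted over the list alone 4 and 0, quantile 2 and 1) (adjusted p = 0.067). Keratinocyte markers had 5 higher and 0 lower of 11 (adjusted over the list alone 5 and 0, quantile 4 and 2) (adjusted p = 0.2) and endothelial markers 1 higher and 0 lower of 6 (adjusted over the list alone 2 and 0, quantile 1 and 0) (adjusted p = 0.2). Fry called all 3 upward with entinostat (adjusted p = 7.4e-05, 0.0021 and 0.0023 in this order, quantile 3.5e-05, 0.041 and 1.9e-04). In DTE against DMSO it called keratinocyte markers downward in deposited values (0.021) and all 3 upward after quantile normalization (1.8e-04, 0.024 and 0.0011).

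A hypothesis was that each treatment has a smaller effect in the presence of the other. Genes were picked on 1 array of each arm and the response was measured on the other arrays, in quantile-normalized values, as the ratio of the median response with the other treatment to that without it. For genes raised by dabrafenib plus trametinib the ratio was 0.499 (0.474 to 0.517 over 3 picks) and for genes it lowered 0.642 (0.621 to 0.667), below the bound of 0.8 set in advance. For genes raised by entinostat it was 1.01 (0.982 to 1.02) and for genes it lowered 0.890 (0.861 to 0.912), above that bound. The response to dabrafenib plus trametinib may thus be smaller with entinostat, while for entinostat the test argued against a reduction past the bound for genes it raised. For genes it lowered each ratio lay below 1, and the bound could not exclude so small a reduction, which stays open. Whether compression on the dimmer DTE arrays contributes was not tested for these ratios.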
